A study of Homo sapiens with 20 samples.

How the data were processed

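Messenger RNA levels were measured in 20 cultures of primary human epidermal keratinocytes with an Affymetrix array of 12625 probe sets, 1 array per culture. The cultures received 0.1 µM dexamethasone or were left untreated, and were collected at 1, 4, 24, 48 and 72 h. The course was run with 2 independent batches of cells, called experiment I and experiment II, so each of the 10 groups held 2 arrays, 1 from each experiment.

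The deposited values are log2 expression levels, 1 per probe set and array, from 1.61 to 14.0. The base of 2 was read from this range, since no label names it. MAS5 and GCOS are named per the submitters' processing notes, with no role, order or version, and neither the step that gave log2 values nor the normalization between arrays is stated. Array medians lay between 5.36 and 5.46, so no further scaling was applied. The plan fixed before the data were examined had taken the values to be linear signals with a pseudocount added. It also provided that values found to be logarithms be used as they are, and they were used without a pseudocount.

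Of the 12625 probe sets, 67 controls were left out, as were 545 with several gene symbols and 1070 with none in the platform's annotation. Of the 10943 probe sets with 1 symbol, 10934 had a gene ID found in the reference gene table of assembly GRCh38.p14, which served for names alone. Genes on the Y chromosome and XIST were left out of all tables. This left 10927 probe sets of 8210 genes, 1928 of them with more than 1 probe set. Each gene was represented by its probe set with the highest mean over all arrays, and sets whose names end in _x_at were used only where a gene had no other. A gene was tested if it stood above the 40th percentile of its array in at least 2 arrays, which 5931 genes did. No column of per-array values was left unused.

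Differences were tested with limma 3.58.1 in R 4.3.3. The model held a mean for each of the 10 groups and a replicate block for the experiment, fitted to all 20 arrays with 9 residual degrees of freedom and empirical Bayes moderation with a variance trend. The block was used because the labels give each array's experiment. It was checked on the data: the correlation across genes between 2 groups of the deviation of experiment I from the group mean ranged from 0.234 to 0.83 over the 45 pairs of groups, with a median of 0.559. The comparisons were dexamethasone against untreated at each of the 5 times, the mean of these 5 effects, the late effect (24, 48 and 72 h) minus the early effect (1 and 4 h), and late against early untreated cultures. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 5931 genes of each comparison, and an adjusted p under 0.05 was called changed. Errors are standard errors (SE) from limma unless named otherwise. Mean levels of groups are log2 values.

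The 24 gene lists cover glucocorticoid receptor targets, corticosteroid receptors and steroid metabolism, interferon response, inflammatory cytokines and NF-kB targets, terminal differentiation and the cornified envelope, basal keratinocytes and hemidesmosome, wound activation with migration and matrix proteolysis, cell cycle, cell cycle inhibitors, apoptosis (promoting and inhibiting genes apart), cholesterol biosynthesis, fatty acid and epidermal lipid synthesis, metallothioneins, immediate early genes and AP-1, EGFR and MAPK feedback, circadian clock, TGF-beta and BMP response, heat shock and unfolded protein response, oxidative stress response, and markers of melanocytes, fibroblasts, Langerhans and immune cells, and endothelium. The 23 lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 184 tests of 23 lists in 8 comparisons. Camera was also run with a correlation estimated for each list. Members were counted by the test over all genes and by the test adjusted over the list alone.

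Named genes were chosen by a rule among those past the threshold. For the mean over 5 times these were the 10 largest rises and 10 largest falls with the same sign in all 10 pairs of treated and untreated arrays. For each time they were the 6 largest rises and falls with the same sign in both experiments, for late minus early the 6 largest each way, and for the untreated cultures the 8 largest each way. Up to 4 members of a list with the smallest p were named with it. Where fewer than 3 genes passed in a direction, the 3 with the smallest p were named as not past the threshold. NR3C1, FKBP5, TSC22D3, PER1, DUSP1 and KLF9 were named whatever their values, but PER1 was not among the genes tested. The comparisons, tests, gene lists and this rule were fixed before the data were examined.

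The procedure was tested on simulated data in which 200 of 5931 genes were changed by 1.5-fold, 2-fold or 4-fold. In a comparison at a single time it recovered 43.3%, 95.5% and 98.5% of them, with 4 unchanged genes called. In the mean of 5 times it recovered 97.0% of the 1.5-fold changes, with 7 unchanged genes called. Late minus early gave 67.2%, 91.0% and 100% and the untreated cultures 89.6%, 97.0% and 100%, with 7 and 10 unchanged genes called. A list moved in the simulated data was found in each of the 4 comparisons, and 0 of the other lists were called. The simulated noise was independent between genes, unlike that of real lists. The simulation therefore gives no rate of false list calls for correlated genes.

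The alternatives tried were pseudocounts of 1.615 and 64.61 on the linear scale, no filter and a filter at the 60th percentile, quantile normalization, centring on array medians, the mean of all probe sets of a gene, every probe set on its own, no variance trend, no replicate block, a replicate block for each time and experiment, only the arrays of the comparison, each array left out in turn, and each experiment left out. Those added after the data were examined were a pseudocount of 16.15, a covariate for the 3′ minus 5′ difference of the GAPDH control probe sets, array weights, the fit without the 72 h arrays, and the fit without the treated 1 h and untreated 24 h arrays of experiment I. Counts of changed genes were also taken over other assignments of the arrays to treatment or time. Array values carry no read depth, so the number of arrays limits the precision. Figures and name matching used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.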

Results

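Primary human epidermal keratinocytes, the main cells of the outer skin layer, were grown in lipid-depleted medium to about 70% confluence. They were then given 0.1 µM dexamethasone, a synthetic glucocorticoid, or nothing. Levels of messenger RNA were measured at 1, 4, 24, 48 and 72 h, with 2 arrays for each of the 10 combinations of time and treatment and 1 array of each pair from each of 2 independent experiments. Across genes, which are not independent replicates, replicate arrays correlated at 0.93 to 0.979. The lowest value was shared by the untreated 24 h and the treated 1 h cultures, where the median difference between experiments was 0.36 and 0.38 on the log2 scale. The 3′ minus 5′ difference of the GAPDH control probe sets, a measure of RNA quality, ranged from 0.70 to 1.65 (mean 1.00, SD 0.24, n = 20) and was highest in the treated 72 h array of experiment I. The experiments differed in 3635 of 5931 genes, and each comparison was made within experiments. After 1 h of dexamethasone 4 genes had changed, after 4 h 65, after 24 h 191, after 48 h 561 and after 72 h 970. All of these genes moved the same way in both experiments. Genes were called by the mean of both differences, so this agreement largely follows from the calls.

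**Figure D1:**
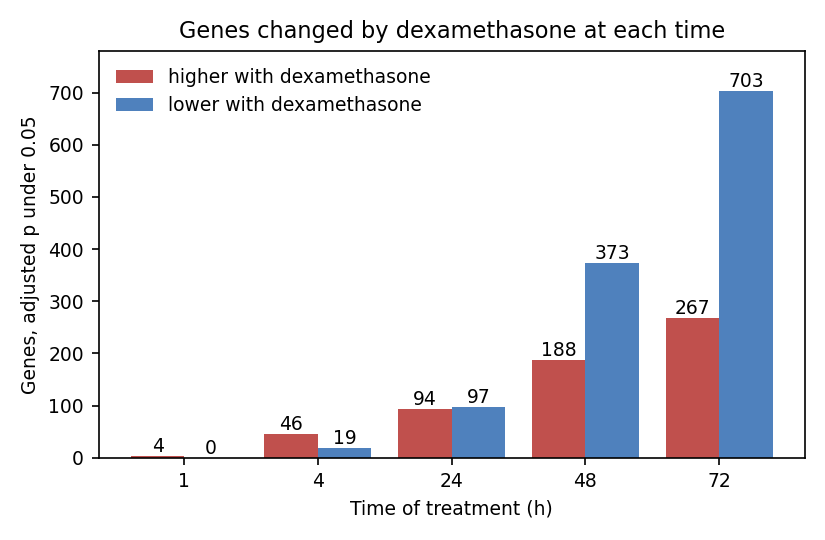
Number of genes higher (red) or lower (blue) with dexamethasone than in parallel untreated cultures at each time in hours, of 5931 genes tested with 2 arrays per group, at an adjusted p under 0.05. Rises outnumbered falls at 4 h (46 and 19), but not without the untreated 4 h array of experiment II (17 and 21), and falls outnumbered rises at 72 h (703 and 267).

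The 1 h comparison asked which transcripts differed soonest after the drug was added. RGS2, a regulator of G protein signalling, rose 16.3-fold, from a mean log2 level of 5.15 to 9.17 (log2 difference 4.03 ± 0.27, n = 2 pairs, adjusted p = 3.69e-06). TSC22D3, the glucocorticoid-induced leucine zipper, rose 6.30-fold (2.66 ± 0.20, adjusted p = 8.41e-06), while its second probe set, at a mean level of 7.27, gave 0.96. SGK1, the serum- and glucocorticoid-regulated kinase, rose by 1.81 ± 0.26 (adjusted p = 0.0112), and KLF9, a Krüppel-like transcription factor, by 1.24 ± 0.20 (adjusted p = 0.0352). In experiments I and II the differences were 3.63 and 4.42 for RGS2 and 0.89 and 1.59 for KLF9. No gene fell. In limma 266 genes had an unadjusted p under 0.05, no more than chance alone would give among the genes tested. The 3 lower genes with the smallest p were HBEGF, a ligand of the epidermal growth factor receptor (−1.17, adjusted p = 0.56), PLAU, the urokinase plasminogen activator (−1.29, adjusted p = 0.575), and CYB561 (−0.47, adjusted p = 0.947). FKBP5, a co-chaperone of the glucocorticoid receptor, differed by 0.51 (adjusted p = 0.947), DUSP1, a phosphatase of MAP kinases, by 1.54 ± 0.41 (adjusted p = 0.807), and NR3C1, the receptor itself, by 0.16 (adjusted p = 0.947).

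Of the 30 measured glucocorticoid receptor targets, 4 rose and 26 did not pass at 1 h (9 rose when adjusted over the list alone). As a set they were higher than other genes, with a median of 0.31 (adjusted p = 5.42e-16, and adjusted p = 0.0559 with an estimated correlation). None of the 8 metallothioneins, small metal-binding proteins with near-identical paralogs, passed over all genes, and 5 rose when adjusted over the list alone. Their median was 0.44 (adjusted p = 3.79e-08, and adjusted p = 0.124 with an estimated correlation), with MT2A at 0.86. Among 36 inflammatory cytokines and NF-kB targets 0 passed by either count, while the set test gave a higher position with a median of 0.10 (adjusted p = 0.0148, and adjusted p = 0.448 with an estimated correlation). That set call ended without the treated 1 h array of experiment I (adjusted p = 0.385) and without the untreated one (adjusted p = 0.216), with no filter on dim genes (adjusted p = 0.173) and with the GAPDH 3′ minus 5′ difference as a covariate (adjusted p = 0.149). Across all genes the 1 h differences of the experiments correlated at −0.111. Without the replicate block 2 genes passed, and leaving out the untreated or the treated 1 h array of experiment II gave 2, while leaving out either untreated 4 h array gave 7. RGS2 and TSC22D3 passed without any single array. SGK1 reached an adjusted p of 0.251 and KLF9 of 0.372 without the untreated 1 h array of experiment II. The calls of TSC22D3 (adjusted p = 0.0841) and KLF9 (adjusted p = 0.104) ended without the block. With array weights those of SGK1 and KLF9 ended (adjusted p of 0.155 and 0.217). That of KLF9 also ended under median centring (adjusted p = 0.0665), quantile normalization (0.0507) and the largest pseudocount (0.0705).

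At 4 h known targets of the receptor were among the largest rises. TSC22D3 rose 18.9-fold (log2 4.24 ± 0.20, n = 2 pairs, adjusted p = 3.24e-08) and RGS2 18.1-fold (4.18 ± 0.27). The second probe set of TSC22D3 gave 1.85 at 4 h, 1.05 at 24 h, 0.88 at 48 h and 0.69 at 72 h. FKBP5 rose by 2.82 ± 0.31 (adjusted p = 0.00027), GLUL, glutamine synthetase, by 2.79, ZBTB16, a zinc finger repressor, by 2.13, RRAD, a small GTPase, by 2.04 and KLF9 by 1.90. Among the falls were DUSP6, the phosphatase of ERK (−2.91, adjusted p = 0.0252), the immediate early gene IER3 (−2.75), PLAU (−2.71 ± 0.32, adjusted p = 0.000383), ODC1, which starts polyamine synthesis (−1.78), the matrix protease MMP3 (−1.48) and the phosphate transporter SLC20A1 (−1.46). DUSP1 differed by 1.48 (adjusted p = 0.148) and NR3C1 by −0.15 (adjusted p = 0.999).

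The receptor targets held 10 rises and 20 members that did not pass at 4 h (18 rises adjusted over the list alone), and were higher as a set with a median of 0.91 (adjusted p = 1.7e-38, and 0.0126 with an estimated correlation). Of 8 metallothioneins 4 rose, among them MT1E by 1.24 and MT1F by 1.06 (7 adjusted over the list alone, median 0.86). Their set test gave an adjusted p of 1.82e-16, and of 0.0498 with an estimated correlation. The list of wound activation, migration and matrix proteolysis had 5 falls among 45 members (9 adjusted over the list alone), with VEGFA at −1.19 and VEGFC at −0.72 beside PLAU and MMP3. It was lower as a set (median −0.14, adjusted p = 0.000147, and adjusted p = 0.335 with an estimated correlation). Of 18 genes of EGFR and MAPK feedback 3 fell, DUSP6, DUSP7 (−0.93) and IER3, with 1 rise and 6 falls when adjusted over the list alone. That set was lower with a median of −0.23 (adjusted p = 0.000147, and adjusted p = 0.484 with an estimated correlation), a call that ended without the untreated array of experiment I (adjusted p = 0.089) or the treated array of experiment II (adjusted p = 0.103). Among 17 cell cycle inhibitors FOXO3 rose by 1.18 (6 rises and 1 fall adjusted over the list alone, median 0.24, adjusted p = 0.00086, and adjusted p = 0.168 with an estimated correlation). In the terminal differentiation list 0 of 50 genes passed by either count, and the set test (median 0.16, adjusted p = 0.00496, and adjusted p = 0.605 with an estimated correlation) ended without the treated 4 h array of experiment I (adjusted p = 0.407). The acute-phase gene SAA1 (1.89) and the receptor TLR2 (1.46) rose in the inflammatory list.

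In all, 46 genes rose and 19 fell at 4 h, and the differences of the 2 experiments correlated at 0.6 across genes. A fit with no replicate block passed 19 genes. Without the untreated arrays of experiments I and II the counts were 33 and 38 (17 rises and 21 falls), and without the treated ones 35 and 15. Of the 13 named genes past the threshold 7 passed without any single array, while the calls of DUSP6, IER3, MMP3, ODC1, RRAD and SLC20A1 ended without the untreated array of experiment I, at adjusted p from 0.0531 (RRAD) to 0.503 (IER3), and without the treated array of experiment II, from 0.0692 (ODC1) to 0.46 (IER3). Without that untreated array DUSP6 was at −1.77 and IER3 at −1.70. Without the block the calls of GLUL (adjusted p = 0.0926), DUSP6, IER3, MMP3, ODC1 and SLC20A1 ended, at adjusted p of up to 0.423. With the larger pseudocounts those of DUSP6 (−1.12 with the largest) and IER3 ended (adjusted p of up to 0.256 and 0.119). Under median centring those of IER3 and MMP3 ended (each adjusted p = 0.0539).

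At 24 h MMP1, interstitial collagenase, fell from a mean level of 7.27 to 3.06 (log2 −4.20 ± 0.33, n = 2 pairs, adjusted p = 8.87e-06). Its treated level lay under 3.36, the lowest 10th percentile of any array, so the size of this fall is limited by the background of the array. ODC1 fell by 3.24 ± 0.33, DUSP6 by 2.79, FSCN1, an actin-bundling protein, by 2.44, ANXA3, an annexin, by 2.43 and G0S2, an inhibitor of a triglyceride lipase, by 2.38. On the other side GLUL rose by 3.05 ± 0.32, SAA1 by 2.94, TSC22D3 by 2.85, TFRC, the transferrin receptor, by 2.62 (adjusted p = 0.0252), RGS2 by 2.57 and RRAD by 2.45. FKBP5 rose by 2.21 and KLF9 by 1.88, while DUSP1 (1.25, adjusted p = 0.138) and NR3C1 (−0.30, adjusted p = 0.395) did not pass.

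Of 45 wound, migration and matrix genes 14 fell and 1 rose at 24 h (20 and 1 adjusted over the list alone), with MMP9 at −2.10 and the protease inhibitor SERPINE2 at −1.90. The riser was EGFR, the receptor of epidermal growth factor, at 0.88. The list's median was −0.33 (adjusted p = 3.42e-11, and adjusted p = 0.0807 with an estimated correlation). Receptor targets held 13 rises and 0 falls (17 rises adjusted over the list alone, median 0.96, adjusted p = 1.09e-20, and 0.0457 with an estimated correlation). Basal and hemidesmosome genes, which anchor keratinocytes to the basement membrane, held 4 falls among 22 members: ITGA6 (−0.99), ITGA2 (−1.02), CDH3 (−1.07) and LAMB3 (−0.91). With 7 falls adjusted over the list alone, that set had a median of −0.08 (adjusted p = 0.00346, and adjusted p = 0.549 with an estimated correlation), and its call ended without the untreated 24 h array of experiment II (adjusted p = 0.0586). The 51 interferon response genes held 4 falls, CASP1 (−1.26), IFI16 (−0.69), IFNGR2 (−0.48) and HLA-F (−0.53), or 8 adjusted over the list alone. Their median was −0.23 (adjusted p = 5.5e-06, and adjusted p = 0.546 with an estimated correlation), at −0.01 in experiment I and −0.42 in experiment II, and the call ended without the untreated 24 h array of experiment II (adjusted p = 0.39).

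Smaller groups also passed the set test at 24 h. Among 18 EGFR and MAPK feedback genes EGFR rose, and DUSP6, DUSP4 (−1.44) and PHLDA1 (−1.43) fell (2 rises and 5 falls adjusted over the list alone, median −0.26, adjusted p = 0.0423, and adjusted p = 0.718 with an estimated correlation). TOB1, an antiproliferative gene, rose by 1.31 among 17 cell cycle inhibitors (3 rises adjusted over the list alone, median 0.24, adjusted p = 0.00423, and adjusted p = 0.257 with an estimated correlation). HSPA5, a chaperone of the endoplasmic reticulum, fell by 0.79 among 20 heat shock and unfolded protein genes (1 rise and 3 falls adjusted over the list alone, median −0.24, adjusted p = 0.0203, and adjusted p = 0.516 with an estimated correlation). Without the untreated 24 h array of experiment I these 3 set calls ended, with adjusted p of 0.488 for EGFR and MAPK feedback, 0.0833 for the inhibitors and 0.0654 for heat shock. EGFR and MAPK feedback also ended without the treated 24 h array of experiment I (adjusted p = 0.183), by smaller margins without 5 arrays of 48 and 72 h, and with the GAPDH covariate (adjusted p = 0.128). Heat shock ended without either array of experiment II, untreated (adjusted p = 0.0701) or treated (adjusted p = 0.134).

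In total 94 genes rose and 97 fell at 24 h, the experiments correlating at 0.479 across genes. With no replicate block 66 genes passed, and the counts were 91 (32 rises and 59 falls) without the untreated and 104 (41 and 63) without the treated array of experiment I, and 40 (24 and 16) without the treated array of experiment II. Without the untreated array of experiment II there were 91 rises and 59 falls, and without the treated 1 h and untreated 24 h arrays of experiment I together 42 and 98. Of 14 named genes past the threshold 11 passed without any single array. The calls of ANXA3, DUSP6 and TFRC ended without the treated array of experiment II (adjusted p of 0.318, 0.208 and 0.191) and without the untreated array of experiment I (0.156, 0.105 and 0.224). ANXA3 was at −1.29 without the treated array of experiment II. Array weights ended them too (adjusted p of 0.0829, 0.0539 and 0.0782). Those of ANXA3 and TFRC ended without the block (adjusted p of 0.146 and 0.0787).

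**Figure D2:**
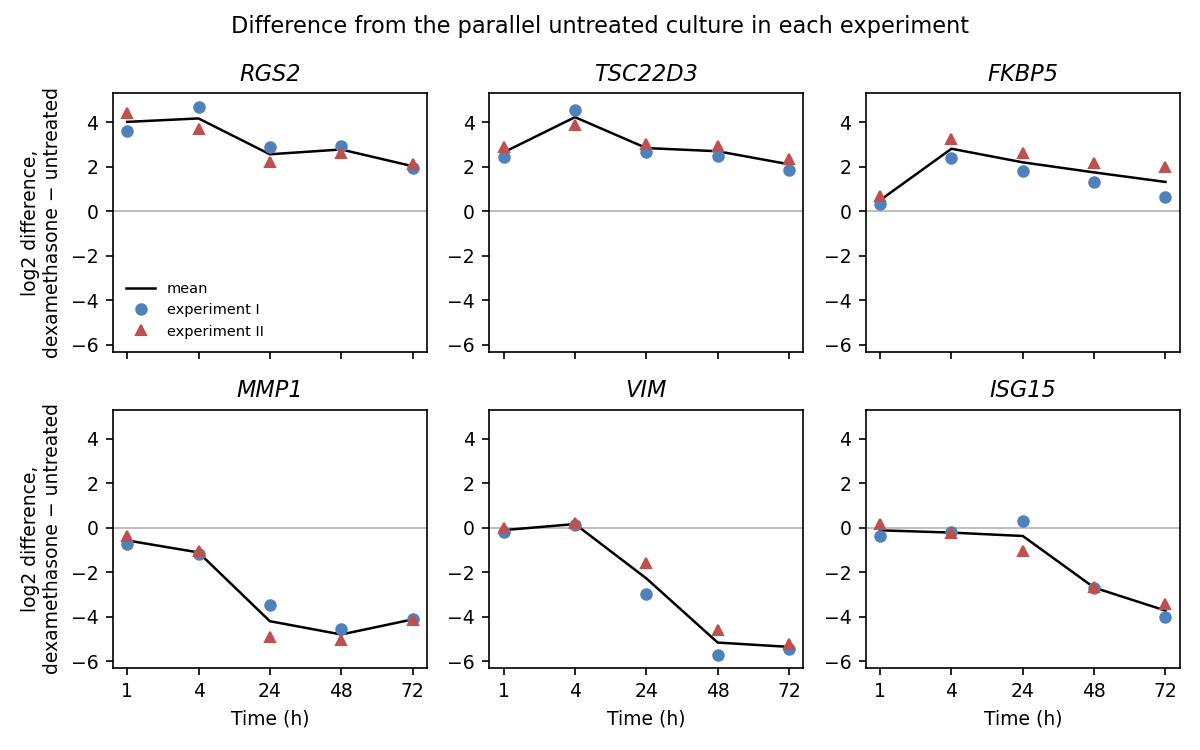
Log2 difference between dexamethasone and the parallel untreated culture at each time in hours for 6 genes, with experiment I as circles, experiment II as triangles and their mean as a line (n = 2 per time). RGS2 and TSC22D3 were above 2 in the mean at each time, while VIM fell to −5.16 at 48 h and ISG15 to −3.73 at 72 h.

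At 48 h the intermediate filament gene VIM and the collagenase MMP1 showed the largest falls. VIM fell from a mean level of 8.04 to 2.88 (log2 −5.16 ± 0.49, n = 2 pairs, adjusted p = 3.65e-05) and MMP1 from 7.44 to 2.64 (−4.80 ± 0.33, adjusted p = 2.07e-06). Both treated levels lay under 3.36, the lowest 10th percentile of any array, so these differences are limited by the background of the array. TNC, the matrix protein tenascin-C, fell by 3.11, MMP9 by 3.06, the interferon-induced IFIT1 by 2.95 and LGALS1, the lectin galectin-1, by 2.91. A second, dim probe set of TNC (mean level 3.51) differed by 0.15. RGS2 (2.78), TSC22D3 (2.71), ZBTB16 (2.62), RRAD (2.43), GLUL (2.29) and HSD11B2, which inactivates cortisol (2.26), rose most. DUSP1 rose by 1.89 ± 0.41 (adjusted p = 0.00863), KLF9 by 2.11 and FKBP5 by 1.76, and NR3C1 was at −0.49 (adjusted p = 0.052) with its other probe sets at 0.09 and −0.47.

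Interferon response genes formed the largest group of falls at 48 h. Of 51 members 35 fell, 0 rose and 16 did not pass (42 falls adjusted over the list alone), including ISG15 (−2.70), IFITM1 (−2.32), OAS2 (−1.99) and IFITM3 (−1.38). The median was −0.97 (adjusted p = 1.1e-29, and adjusted p = 0.103 with an estimated correlation), at −1.02 in experiment I and −0.80 in experiment II. Of 45 wound, migration and matrix genes 19 fell and 2 rose (21 and 3 adjusted over the list alone, median −0.48, adjusted p = 3.11e-11, and adjusted p = 0.0807 with an estimated correlation). Among 22 basal genes 6 fell, CDH3 by 1.40 and COL7A1 by 0.91 for example (8 adjusted over the list alone, median −0.37, adjusted p = 4.21e-05, and adjusted p = 0.407 with an estimated correlation). Cell cycle genes held 8 falls and 0 rises among 50, with MCM6 (−1.55), CDK4 (−0.62), TYMS (−1.09) and RFC4 (−1.06), or 15 falls adjusted over the list alone. That list had a median of −0.26 (adjusted p = 2.5e-05, and adjusted p = 0.551 with an estimated correlation).

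Receptor targets held 17 rises and 1 fall at 48 h (21 and 1 adjusted over the list alone), with CEBPD at 1.54. Their median was 0.92 (adjusted p = 5.42e-16, and adjusted p = 0.0559 with an estimated correlation), at 0.68 in experiment I and 1.27 in experiment II. Terminal differentiation genes, which build the outermost layer, held 6 rises and 2 falls among 50 (10 and 3 adjusted over the list alone). TGM1, a transglutaminase of the cornified envelope, rose by 1.68 and the envelope protein PPL by 0.98, while the serpin SERPINB3 fell by 1.49 and CRABP2, a retinoic acid binding protein, by 1.68. The set was higher with a median of 0.28 (adjusted p = 0.00534, and adjusted p = 0.605 with an estimated correlation), which ended without the treated 48 h array of experiment II (adjusted p = 0.0611). Among 21 immediate early and AP-1 genes FOSL2 (0.72) and EGR3 (1.42) rose (3 rises and 1 fall adjusted over the list alone, median 0.38, adjusted p = 0.00346, and adjusted p = 0.605 with an estimated correlation), a call that ended without the same array (adjusted p = 0.0682). In the list of 12 clock genes RORA, a nuclear receptor, rose by 1.54 (4 rises adjusted over the list alone, median 0.16, adjusted p = 0.0423, and adjusted p = 0.296 with an estimated correlation). The clock call ended without any of the 4 arrays of 48 h, at adjusted p of up to 0.0712, and without either untreated array of 72 h. It also ended under the stricter filter on dim genes (median 0.13, adjusted p = 0.186), and under both quantile normalization (adjusted p = 0.0502) and median centring (adjusted p = 0.0509).

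The 48 h comparison had 188 rises and 373 falls, and the experiments correlated at 0.777 across genes. The GAPDH 3′ minus 5′ difference was higher with dexamethasone by 0.33 in experiment I and 0.29 in experiment II at this time. When the replicate block was dropped 214 genes passed, and 213 and 280 passed without the untreated array of experiment I or II and 166 without the treated array of experiment II. Of 15 named genes past the threshold 11 passed without any single array, and the calls of DUSP1 (adjusted p = 0.166), FKBP5 (adjusted p = 0.0593), HSD11B2 (adjusted p = 0.0572) and LGALS1 (adjusted p = 0.062) ended without the treated 48 h array of experiment II, those of DUSP1 and LGALS1 also without the untreated array of experiment I. The call of GLUL ended without the block (adjusted p = 0.055).

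After 72 h VIM was lower by 5.36 ± 0.49 on the log2 scale (n = 2 pairs, adjusted p = 9.4e-06), with treated levels of VIM (2.91) and MMP1 (3.02) again under that lowest 10th percentile. S100A8, a calcium-binding alarmin, fell 30.1-fold from a level of 10.6 to 5.71 (−4.91 ± 0.40, adjusted p = 3.51e-06), as did S100A7, psoriasin (−4.57), LGALS1 (−4.43) and MMP1 (−4.12). ISG15, a ubiquitin-like protein induced by interferon, fell from 10.5 to 6.82 (−3.73 ± 0.27, adjusted p = 1.38e-06), with a second probe set at −2.04. The largest rises were AZGP1 (2.77, adjusted p = 0.0132), arginase ARG1 (2.74 ± 0.85, adjusted p = 0.041), the protease inhibitor SPINK1 (2.67), the late cornified envelope gene LCE2B (2.42), the channel-activating protease PRSS8 (2.21) and ZNF165 (2.21). In experiments I and II ARG1 was higher by 1.42 and 4.07. TSC22D3 rose by 2.12, KLF9 by 1.43, DUSP1 by 1.55 (adjusted p = 0.0188) and FKBP5 by 1.33 (adjusted p = 0.00988). NR3C1 fell by 0.57 ± 0.15 (adjusted p = 0.0165), with its other probe sets at −0.18 and −0.65. The difference and SE of DUSP1 were nearly those of 1 h (1.54 ± 0.41), where it did not pass. The adjustment is milder where more genes change, so calls at separate times are not directly comparable.

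Of 51 interferon response genes 40 fell, 1 rose and 10 did not pass at 72 h (41 and 2 adjusted over the list alone). IFITM1 (−3.41), IFITM3 (−2.41) and IFI27 (−2.39) were among the falls, and OASL was the rise (0.92). The median was −1.13 (adjusted p = 2.68e-26, and adjusted p = 0.123 with an estimated correlation), at −1.22 in experiment I and −1.07 in experiment II. Wound, migration and matrix genes held 22 falls and 1 rise among 45 (25 and 2 adjusted over the list alone), with MMP9 (−3.28), FGFBP1, a carrier of fibroblast growth factors (−2.48), and TIMP1 (−1.79) lower and TIMP2 (1.11) higher. They had a median of −0.70 (adjusted p = 3.95e-11, and adjusted p = 0.0807 with an estimated correlation). Basal genes held 10 falls and 0 rises among 22 (13 falls adjusted over the list alone), ITGA2 at −1.25, COL7A1 at −1.15, ITGA6 at −0.98 and CD151 at −0.78. Their median was −0.56 (adjusted p = 1.35e-05, and adjusted p = 0.406 with an estimated correlation), at −0.77 in experiment I and −0.39 in experiment II.

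Cell cycle genes held 12 falls and 0 rises among 50 at 72 h (14 falls adjusted over the list alone), among them MCM6 (−1.40), a subunit of the replicative helicase, CCND2 (−0.87), TYMS (−0.91) and RFC4 (−0.87). The median was −0.26 (adjusted p = 0.000452, and adjusted p = 0.605 with an estimated correlation), and the call ended without the untreated 72 h array of experiment II (adjusted p = 0.305). Receptor targets held 15 rises and 1 fall (18 and 1 adjusted over the list alone, median 0.77, adjusted p = 3.79e-08, and adjusted p = 0.151 with an estimated correlation), at a median of 0.47 in experiment I and 1.15 in experiment II. In the terminal differentiation list 6 genes rose, TGM1 (1.64) and PPL (0.98) among them, and 6 fell, SERPINB3 (−2.01) and CRABP2 (−2.22) among them (9 and 7 adjusted over the list alone). As a set it did not pass (median 0.21, adjusted p = 0.144). The inflammatory list had 4 falls, S100A8, S100A7, S100A9 (−3.06) and the elastase inhibitor PI3 (−1.93), and 2 rises, IL1RN (0.81) and NFKBIA (1.12), which antagonise interleukin-1 and NF-kB. Its median was 0.01 and its mean −0.31, and as a set it did not pass (adjusted p = 0.917). Among 21 immediate early and AP-1 genes FOSL2 (0.78), EGR3 (1.42), ZFP36 (1.603) and NR4A3 (0.41) rose (6 rises and 1 fall adjusted over the list alone, median 0.34, adjusted p = 0.024, and adjusted p = 0.718 with an estimated correlation). This call ended without the untreated array of experiment I (adjusted p = 0.0754) or the treated array of experiment II (adjusted p = 0.439).

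Of the 5931 genes 267 rose and 703 fell at 72 h, and the experiments correlated at 0.76 across genes. The GAPDH 3′ minus 5′ difference was higher with dexamethasone by 0.46 in experiment I and 0.06 in experiment II. Of 7 measured fibroblast markers VIM and FAP (−1.58) fell and COL1A1 (−0.02), PDGFRA (0.32) and THY1 (−0.23) did not pass, while 0 of 5 melanocyte markers passed at any time. Without the replicate block 322 genes passed, and 507 and 561 passed without the untreated array of experiment I or II and 529 without the treated array of experiment II. Of 17 named genes past the threshold 10 passed without any single array, and the calls of ARG1 (adjusted p = 0.319), AZGP1 (0.137), DUSP1 (0.175), FKBP5 (0.133), LCE2B (0.224), NR3C1 (0.0689) and ZNF165 (0.146) ended without the treated 72 h array of experiment II, all but that of FKBP5 also without the untreated array of experiment I. Without that treated array ARG1 was at 1.49, LCE2B at 1.23, ZNF165 at 1.08 and FKBP5 at 0.84, and without the treated array of experiment I ZNF165 was at 3.34. The calls of ARG1 (adjusted p = 0.0928), FKBP5 (0.0767), LCE2B (0.0503) and NR3C1 (0.179) ended without the block too. With the largest pseudocount those of ARG1 and FKBP5 ended (adjusted p of 0.0849 and 0.107). With array weights those of ARG1 and DUSP1 ended (adjusted p of 0.0709 and 0.0504). The call of ARG1 also ended with the pseudocount of 16.15 (adjusted p = 0.0558).

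**Figure D3:**
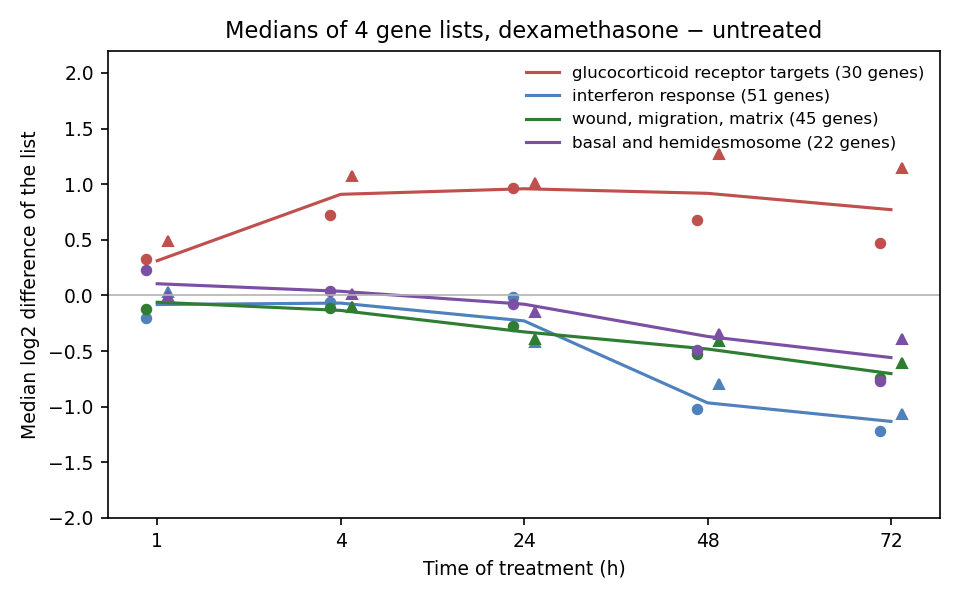
Median log2 difference between dexamethasone and untreated cultures over the measured members of 4 gene lists at each time in hours, with experiment I as circles, experiment II as triangles and lines for the median of the mean effects. Interferon response genes were at −0.97 at 48 h and −1.13 at 72 h, while receptor targets were at 0.31 at 1 h and 0.96 at 24 h.

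More changed genes were shared between neighbouring times than independent calls would give. In detail, 125 rose at both 48 and 72 h and 341 fell at both, against 8.46 and 44.2 under independence, and 0 moved in opposite directions. At both 24 and 48 h 69 rose and 80 fell, against 2.98 and 6.10, and at both 4 and 24 h 23 rose and 8 fell, against 0.73 and 0.31. Each time had its own untreated arrays, so the differences themselves share no array. The error of each gene was estimated from all 20 arrays, however, so calls at separate times are not fully independent. The transcription factor NFE2L1, singled out after its values were seen, rose by 0.62 at 4 h and fell by 0.59 at 72 h, the only gene called in opposite directions at 2 times. The treatment effect differed between times in 218 genes and differed from 0 at any time in 847 (F tests in limma).

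The mean of the 5 effects asked which genes dexamethasone moved over the whole course. Among genes higher in all 10 pairs, RGS2 (log2 3.12 ± 0.12, n = 10 pairs from 2 experiments, adjusted p = 7.17e-10) and TSC22D3 (2.91 ± 0.09, adjusted p = 8.7e-11) rose most. After them came GLUL (2.19), RRAD (1.93), BCL6, a transcriptional repressor (1.81), FKBP5 (1.72 ± 0.14), KLF9 (1.71 ± 0.09), SAA1 (1.67), DUSP1 (1.54 ± 0.18) and HSD11B2 (1.37). The 10 pairs are 5 times in 2 experiments, not 10 independent batches of cells, though the errors treat them as independent. In experiments I and II RGS2 was at 3.21 and 3.02, FKBP5 at 1.30 and 2.14 and SAA1 at 1.21 and 2.13. Among genes lower in all 10 pairs, MMP1 (−2.96 ± 0.15, adjusted p = 1.54e-08), ODC1 (−2.24), PLAU (−2.11), IER3 (−1.98) and DUSP6 (−1.91) fell most. FGFBP1 (−1.33), IFITM1 (−1.32), the secretory chaperone SCG5 (−1.16), IFIT3 (−1.10) and SERPINE2 (−1.08) followed. The ranking leaves out genes without that sign in all pairs, so it need not hold the largest mean falls. S100A8, left out in this way, fell further than FGFBP1. VIM and MMP9, with large falls at 48 and 72 h, are also absent from the ranking. The 20 ranked genes were chosen for the same direction in all 10 pairs, so that agreement is not a separate result. NR3C1 fell by 0.27 ± 0.07 (adjusted p = 0.0091), with other probe sets at −0.02 and −0.34. The 2 dim probe sets of BCL6 were at 0.08 and 0.05, and the second probe set of TSC22D3 was at 1.085.

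Over the course 24 of 30 receptor targets rose and ANXA1, annexin A1, fell by 0.38 (25 and 1 adjusted over the list alone, median 0.89, adjusted p = 8.6e-21, and 0.0457 with an estimated correlation). Interferon genes held 40 falls and 1 rise, SOCS1 (0.26), an inhibitor of cytokine signalling (44 and 2 adjusted over the list alone, median −0.48, adjusted p = 7.15e-23, and adjusted p = 0.147 with an estimated correlation). Wound, migration and matrix genes held 25 falls and 3 rises (29 and 4 adjusted over the list alone, median −0.35, adjusted p = 3.42e-11, and adjusted p = 0.0807 with an estimated correlation). Basal genes held 8 falls by both counts (median −0.16, adjusted p = 0.000931, and adjusted p = 0.516 with an estimated correlation), and cell cycle genes 11 falls and 1 rise by both counts (median −0.10, adjusted p = 0.00559, and adjusted p = 0.718 with an estimated correlation). The cell cycle call ended without the untreated 72 h array of experiment II (adjusted p = 0.0534) and with the GAPDH covariate (adjusted p = 0.0854). Cell cycle inhibitors held 7 rises, FOXO3 (0.86), TOB1 (0.82) and GADD45B (0.81) among them, and 1 fall (8 and 2 adjusted over the list alone, median 0.18, adjusted p = 0.00879, and adjusted p = 0.313 with an estimated correlation). Of 8 metallothioneins 5 rose (6 adjusted over the list alone, median 0.25, adjusted p = 0.00334, and adjusted p = 0.417 with an estimated correlation).

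Terminal differentiation genes held 14 rises and 3 falls over the course (19 and 4 adjusted over the list alone), with TGM1 at 0.95 and PPL at 0.60 against SERPINB3 at −0.86 and CRABP2 at −0.91. The set test (median 0.12, adjusted p = 0.0218, and adjusted p = 0.706 with an estimated correlation) ended without 4 single arrays: untreated 72 h (adjusted p = 0.0917) and treated 4 h (adjusted p = 0.0571) of experiment I, and untreated 1 h (adjusted p = 0.103) and treated 72 h (adjusted p = 0.104) of experiment II. The inflammatory list held 7 rises, SAA1, NFKBIA (1.10) and IL1RN (0.57) among them, and 7 falls, S100A8 (−1.68) among them, with a median of 0.02, a mean of −0.03 and no call (adjusted p = 0.809). EGFR and MAPK feedback held 5 rises and 6 falls (median −0.10, adjusted p = 0.273), immediate early genes 3 rises and 1 fall (adjusted p = 0.0799) and clock genes 4 rises and 1 fall (adjusted p = 0.107). Among 10 Langerhans and immune cell markers CD68, a lysosomal protein, fell by 0.21, and CLDN5 rose by 0.19 among 3 measured endothelial markers, too few to test.

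In this mean 461 genes rose and 735 fell, and the experiments correlated at 0.816 across genes. Dropping the replicate block left 576 genes. With the 10 arrays of experiment I alone 10 passed (5 rises and 5 falls) and of experiment II alone 45 (35 and 10). Each experiment alone was fitted with a simpler model of time and treatment, with 1 effect for all times. Changes of the effect with time thus entered the error, and these counts are not comparable with those of the main model. Leaving out the 72 h arrays gave 631 genes, and NR3C1 then no longer passed (adjusted p = 0.144), nor did it without the block (adjusted p = 0.122). IFITM1 was at −0.79 without the 72 h arrays. The 21 named genes past the threshold passed without any single array. Of these RGS2, TSC22D3, KLF9, DUSP1, PLAU and IER3 passed in each experiment alone in the simpler model. There HSD11B2 was at 0.88 (adjusted p = 0.133) without experiment II. FKBP5 was at 1.12 with the pseudocount of 16.15 and at 0.58 with that of 64.61. When treatment was exchanged at random within the 10 pairs, 18 of 100 assignments called at least 8 lists at the preset correlation, the number of the real assignment. Of the 51 list calls at the preset correlation in the 8 comparisons, 4 held with an estimated one, namely the receptor targets at 4 h, at 24 h and in the mean and the metallothioneins at 4 h.

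The late minus early comparison tested directly whether the effect of dexamethasone at 24, 48 and 72 h differed from that at 1 and 4 h. Its 10 pairs came from 2 experiments. The effect was lower late than early for VIM (−4.29 ± 0.45, n = 10 pairs, adjusted p = 0.000176), MMP1 (−3.53 ± 0.30, adjusted p = 3.23e-05), S100A8 (−3.02), MMP9 (−2.65), S100A7 (−2.54) and TNC (−2.48). It was higher late for TFRC (1.98, adjusted p = 0.0389), the transcription factor EGR3 (1.92), SPINK1 (1.79), HSD11B2 (1.63), the mucin MUC1 (1.597) and the heme oxygenase HMOX1 (1.44, adjusted p = 0.0468). Other probe sets of MUC1 ranged from 0.11 to 2.08, and the dim second one of TNC was at 0.13. TSC22D3 was higher at both ends but less so late (−0.89 ± 0.19, adjusted p = 0.00909), by −0.54 in its second probe set. The differences for NR3C1 (−0.46, adjusted p = 0.0505), FKBP5 (0.10, adjusted p = 0.872), DUSP1 (0.05, adjusted p = 0.959) and KLF9 (0.23, adjusted p = 0.504) did not pass.

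Of 51 interferon genes 32 had a lower and 0 a higher effect late (36 lower adjusted over the list alone), OAS2 at −1.89 and ISG15 at −2.09 for example. The median was −0.79 (adjusted p = 1.82e-25, and adjusted p = 0.124 with an estimated correlation). Wound, migration and matrix genes held 17 lower and 0 higher effects among 45 (19 and 1 adjusted over the list alone, median −0.28, adjusted p = 4.65e-09, and adjusted p = 0.123 with an estimated correlation). In the basal list 9 of 22 effects were lower, CDH3 at −1.33 for example (13 adjusted over the list alone, median −0.44, adjusted p = 2.11e-07, and adjusted p = 0.296 with an estimated correlation). Cell cycle genes held 6 lower effects among 50, MCM6 at −1.31 and TYMS at −0.79 among them (11 adjusted over the list alone, median −0.22, adjusted p = 1.13e-05, and adjusted p = 0.533 with an estimated correlation). Of 8 metallothioneins 5 were lower, MT1E at −0.95 and MT1B at −0.83 among them (6 adjusted over the list alone, median −0.57, adjusted p = 3.87e-06, and adjusted p = 0.199 with an estimated correlation). Among 21 immediate early genes EGR3 and IER2 (1.10) were higher by both counts (median 0.28, adjusted p = 0.00473, and adjusted p = 0.605 with an estimated correlation), and the call ended without the untreated 4 h array of experiment I (adjusted p = 0.105) or the treated 4 h array of experiment II (adjusted p = 0.0691). Receptor targets held 4 higher effects, such as ZBTB16 (1.28), and 3 lower, such as RGS2 (−1.64) and ANXA1 (−1.04), with no call (4 and 5 adjusted over the list alone, adjusted p = 0.412).

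Effects were higher late in 114 genes and lower in 358, and the experiments correlated at 0.563 across genes. Without the replicate block 136 genes passed, without the untreated 1 h or the treated 4 h array of experiment I 304 and 280, and without the treated 1 h and untreated 24 h arrays of experiment I together 718. Leaving out the 72 h arrays gave 259 genes, with S100A8 at −2.01 and S100A7 at −1.47. Of 13 named genes past the threshold 11 passed without any single array, while the calls of HMOX1 and TFRC ended in most fits with a single array left out. With the GAPDH covariate TFRC was at 1.12 (adjusted p = 0.122), and without the treated 1 h and untreated 24 h arrays of experiment I at 1.46 (adjusted p = 0.115). Without the 72 h arrays the calls of HMOX1 (adjusted p = 0.117) and TSC22D3 (adjusted p = 0.0936) ended. Without the block those of TFRC, HMOX1, HSD11B2, S100A7 and TSC22D3 ended, at adjusted p of 0.106, 0.127, 0.0534, 0.0943 and 0.412. Array weights ended the calls of TFRC (adjusted p = 0.0686) and HMOX1 (adjusted p = 0.0559). That of HMOX1 also ended under median centring (adjusted p = 0.0603) and with no filter (adjusted p = 0.0508).

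Untreated cultures were compared between late (24, 48 and 72 h) and early (1 and 4 h) times as the background of change in culture. The 10 arrays came from 2 experiments. G0S2 (2.19 ± 0.25, n = 10 arrays, adjusted p = 0.00038), the calcium-binding S100P (2.08), the small proline-rich SPRR2D (2.08 ± 0.36, adjusted p = 0.00468), AZGP1 (1.92), cystatin M (CST6, 1.79), lipocalin-2 (LCN2, 1.67), trichohyalin (TCHH, 1.66) and CCNA1 (1.61) rose most, though a second probe set of CST6, at a mean level of 6.23, gave 0.08. The largest falls were in the xenobiotic oxidases CYP1A1 (−2.31 ± 0.35, adjusted p = 0.0024) and CYP1B1 (−2.05), the water channel AQP3 (−1.75 ± 0.16, adjusted p = 0.00011), the basal keratin KRT15 (−1.46, adjusted p = 0.0477), ODC1 (−1.39), FGFBP1 (−1.34), IGFBP2 (−1.24) and MMP3 (−1.22). Other probe sets of CYP1A1 gave −0.90 and −2.35. CYP1B1, whose late level was near the floor of the array (3.24 at 72 h), was at −1.20 with the pseudocount of 16.15 and −0.57 with that of 64.61. NR3C1 (0.31, adjusted p = 0.0716), FKBP5 (−0.32, adjusted p = 0.406), TSC22D3 (−0.05, adjusted p = 0.878), DUSP1 (0.08, adjusted p = 0.895) and KLF9 (0.07, adjusted p = 0.812) did not pass.

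Among 50 terminal differentiation genes 10 rose and 2 fell with time (14 and 2 adjusted over the list alone), ECM1 (0.80) and the lipoxygenase ALOX12B (1.14) among the rises. The median was 0.23 (adjusted p = 1.11e-06, and adjusted p = 0.406 with an estimated correlation). Cell cycle genes held 11 falls and 1 rise among 50 (13 and 4 adjusted over the list alone), with the mitotic genes CCNB1 (−1.18), CCNB2 (−0.82), UBE2C (−0.54) and PLK1 (−0.34) lower. Their median was −0.10 (adjusted p = 0.00534, and adjusted p = 0.718 with an estimated correlation), and the call ended without the untreated 4 h (adjusted p = 0.158) or 72 h (adjusted p = 0.233) array of experiment I, with the GAPDH covariate (adjusted p = 0.105) and under the stricter filter on dim genes (adjusted p = 0.0797). Of 8 metallothioneins 3 rose, MT2A by 0.48 among them (5 adjusted over the list alone, median 0.28, adjusted p = 0.000494, and adjusted p = 0.385 with an estimated correlation). In 17 oxidative stress genes 4 fell, AKR1C3 (−1.11) and AKR1B10 (−0.77) among them (8 falls and 2 rises adjusted over the list alone, median −0.19, adjusted p = 0.0241, and adjusted p = 0.407 with an estimated correlation). The list of 21 TGF-beta and BMP genes held 3 rises, BAMBI (1.03), INHBA (1.13) and LTBP2 (0.50), or 5 adjusted over the list alone (median 0.11, adjusted p = 0.00731, and adjusted p = 0.191 with an estimated correlation). Among 18 EGFR and MAPK feedback genes DUSP7 (0.54) and ETV5 (0.53) rose (3 adjusted over the list alone, median 0.28, adjusted p = 0.0172, and adjusted p = 0.652 with an estimated correlation). The last 3 calls ended without some untreated arrays: oxidative stress without that of 24 h (adjusted p = 0.0619) or 48 h (adjusted p = 0.0516) of experiment II, TGF-beta without that of 1 h of experiment I (adjusted p = 0.0826), and EGFR and MAPK feedback without those of 1 h (adjusted p = 0.194) and 24 h (adjusted p = 0.114) of experiment I and 4 h (adjusted p = 0.33) and 72 h (adjusted p = 0.0504) of experiment II. Under the stricter filter they ended as well, at adjusted p of 0.217, 0.0878 and 0.12. Of 51 interferon genes GBP1 (−0.86) and PSMB10 (−0.40) fell, with no set call (adjusted p = 0.781).

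With time 214 genes rose and 103 fell in untreated cultures, and the experiments correlated at 0.508 across genes. Dropping the replicate block left 68 genes, and the count was 209, 185, 144, 86, 162 and 171 without the untreated arrays of 1 h and 48 h of experiment I and of 1, 4, 48 and 72 h of experiment II. With the GAPDH covariate there were 388 rises and 282 falls. Leaving out the 72 h arrays gave 155 genes and ended the set calls of the metallothioneins (adjusted p = 0.0675), of oxidative stress and of EGFR and MAPK feedback (each adjusted p = 0.0556). Of 16 named genes 11 passed without any single array, while the calls of AZGP1, CST6, IGFBP2, KRT15 and LCN2 ended, at adjusted p of 0.0963, 0.0676, 0.0948, 0.23 and 0.0599 without the untreated 4 h array of experiment II. Without the block these 5 calls and those of AQP3 and ODC1 ended, at adjusted p from 0.0535 (LCN2) to 0.4 (KRT15). That of KRT15 also ended with only the arrays of the comparison (adjusted p = 0.102), with array weights (0.0751), under median centring (0.0616), with no filter (0.0518) and with the largest pseudocount (0.0557). That of AZGP1 ended with the largest pseudocount (0.0611) and without the 72 h arrays (0.0584).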

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

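The counts over other assignments of arrays, the test of a rise in untreated cultures and the test against change with time at 1 h were set before their results were seen. The tests of RNA quality, of fibroblast loss and of exchanged arrays were chosen after the results were seen.

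The effect of dexamethasone differed between late and early times, by a direct test of that difference, in 472 genes. The named ones were TFRC (1.98), EGR3 (1.92), SPINK1 (1.79), HSD11B2 (1.63), MUC1 (1.597), HMOX1 (1.44), VIM (−4.29), MMP1 (−3.53), S100A8 (−3.02), MMP9 (−2.65), S100A7 (−2.54), TNC (−2.48) and TSC22D3 (−0.89). List medians that differed at the preset correlation were those of the interferon response (−0.79), basal genes (−0.44), wound activation and matrix genes (−0.28), the cell cycle (−0.22), the metallothioneins (−0.57) and immediate early genes (0.28), with adjusted p of 0.124, 0.296, 0.123, 0.533, 0.199 and 0.605 in that order with an estimated correlation. The fibroblast markers (−0.23, adjusted p = 0.0335, and adjusted p = 0.416 with an estimated correlation) also differed, with falls in VIM, which the wound list holds too, and FAP (−1.45). That last call ended without the untreated or treated 1 h array of experiment I (adjusted p of 0.117 and 0.115), by smaller margins without 5 other arrays, with no filter on dim genes (median −0.006, adjusted p = 0.319), with the GAPDH covariate (adjusted p = 0.0736), under quantile normalization (adjusted p = 0.0508) and without the treated 1 h and untreated 24 h arrays of experiment I together (adjusted p = 0.242).

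Other choices of 2 early times in each experiment were tested on the differences within pairs. At least as many genes as with the real choice passed in 3 of 100 splits, the real one included. This share is low but does not exclude chance, as 1 other choice gave a much larger count. The real count in that model was 391 and the highest of the others 655. The split with 655 genes set 4 and 24 h as early in experiment I and 1 and 4 h in experiment II, which puts the 1 h pair and the 24 h pair of experiment I, each holding an array far from its replicate, on exchanged sides. Another, which set 48 and 72 h against 1, 4 and 24 h in both experiments, is a division by time as well. In the untreated cultures 1 of 100 splits, the real one, gave as many genes (221, highest other 168), which argues against chance for that count. With treatment exchanged within pairs, 1 of 100 splits, the real one, gave as many changed genes over the 5 times (926 in a model of time, experiment and treatment, highest other 318). This argues against chance for that count. The splits concern total counts in simpler models and do not tell which genes changed. For the number of lists called at the preset correlation chance cannot be excluded, since 18 of 100 splits gave as many (real 8, median of the others 5, highest other 11).

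SAA1 had a larger mean effect in experiment II than in experiment I (difference 0.93, adjusted p = 0.0308), the only gene of 5931 past the threshold in that test. At an unadjusted p under 0.05 there were 281 genes, no more than chance alone would give. Probe sets with no gene symbol or several, outside all comparisons, also carried a signal at 72 h. Of 991 tested, 128 changed, 41 up and 87 down. The 2 largest falls were at −5.51 and −3.03 and the 2 largest rises at 2.29 and 1.59.

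Interferon response genes fell at 72 h, with 40 of 51 lower. RNA quality of the treated arrays is argued against by experiment II, where the GAPDH 3′ minus 5′ difference moved by 0.06 and the median member was at −1.07, and by the fit with that difference as a covariate (median −1.28, 40 members lower). A rise in the untreated cultures alone is argued against by the treated cultures themselves, where the median member changed by −1.06 from 1 and 4 h to 72 h and 45 of 51 were lower, against 0.08 in untreated cultures. As a hypothesis found and tested on the same data, the pattern may reflect a lower interferon response under prolonged dexamethasone. The set test's adjusted p of 0.123 with an estimated correlation stays a limit on how far these genes count as independent.

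VIM, LGALS1 and TNC fell at 72 h. Loss of fibroblasts from the treated cultures would lower other fibroblast markers about as far, but the median of the other 6 tested was 0.071, with COL1A1 at −0.02 and a level of 7.87 in untreated cultures, and COL1A2 and COL3A1 below the 40th percentile there (3.53 and 3.32). FAP, at −1.58 (from 5.83 to 4.25), is the exception among the 6. The prediction holds only for markers whose signal came from fibroblasts, which is not known for these. Signal from other cells would stay unchanged despite a loss, so the median alone cannot decide against it. RNA quality is argued against by experiment II, where the median of the 3 genes was −4.54, and by the covariate fit (−5.01). As a hypothesis the fall may lie within the keratinocytes, and no test in these data localises it.

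The experiments differed at 1 h, where their effects correlated at −0.111 across genes. An exchange of the treated 1 h and untreated 24 h arrays of experiment I is argued against by TSC22D3, KLF9, DUSP1 and FKBP5, whose median was 1.14 higher in the array labelled treated 1 h than in the untreated 1 h array, while the untreated 24 h array stood at 0.01. A treated culture further along the change of untreated cultures with time is argued against by a correlation of −0.195 across genes with that change in experiment II. Both arrays deviated alike, with a correlation of 0.582 across genes, and what they share stays open. No other biological explanation was tested.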

How the results depend on the processing

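The fits with a pseudocount of 16.15, the GAPDH covariate, array weights, without the 72 h arrays and without the treated 1 h and untreated 24 h arrays of experiment I were chosen after the data were seen, and the other alternatives before. Under all alternatives together 1649 values of called lists kept direction and call, 124 lost the call and 0 reversed. Of the named genes' values 14293 kept direction and side of the threshold, 1559 lost the call, 31 gained it and 26 reversed. These totals do not measure stability, since many of the values could not change direction. Leaving out an array of another time does not alter a difference at a single time, only its error. The largest rises and falls were also chosen for the same sign in both experiments. The changed filters, normalizations and probe set summaries and the fit with no variance trend kept every count of genes within 1.5 times. Array weights did not.

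The replicate block removes differences between experiments from the error. Without the replicate block 2 genes passed at 1 h, 19 at 4 h, 66 at 24 h, 214 at 48 h, 322 at 72 h, 576 in the mean, 136 for late minus early and 68 in untreated cultures. A replicate block for each time and experiment gave 10 at 1 h. With only the arrays of the comparison 16, 204, 311 and 877 genes passed at 1, 4, 24 and 48 h. The GAPDH covariate gave 852 at 48 h and 670 in untreated cultures, and array weights gave 2, 135 and 1030 at 1, 4 and 48 h. Without the 72 h arrays, and so with fewer times, the mean had 631, late minus early 259 and untreated cultures 155. Without the treated 1 h and untreated 24 h arrays of experiment I late minus early had 718. With a correlation estimated for each list 4 list calls held. Beyond the block and the missing times, the cause was not tested.

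Leaving out replicates in turn, where a lone array was assumed to vary like the others, gave 2 to 7 genes at 1 h, 15 to 69 at 4 h, 40 to 215 at 24 h, 166 to 613 at 48 h, 507 to 1071 at 72 h, 10 to 1422 in the mean, 280 to 563 for late minus early, 86 to 370 in untreated cultures and 47 to 62 list calls. The low end of the mean came from leaving out experiment II whole. That fit used a simpler model of time and treatment with 1 effect for all times, so its count is not comparable with the others.

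Reversed values belonged to small differences that had not passed, and the cause was not tested. For late minus early FKBP5 was at −0.144 with 4 times the pseudocount, −0.087 with the pseudocount before log2 and −0.062 to 0.26 without single arrays, DUSP1 at −0.263 to 0.358, and KLF9 at −0.02 without the 2 arrays of experiment I. In untreated cultures TSC22D3 was at 0.051 without the 72 h arrays and −0.172 to 0.082 without single arrays, DUSP1 at −0.022 without the 2 arrays and −0.234 to 0.388, and KLF9 at −0.014 with the GAPDH covariate and −0.028 to 0.162. NR3C1 at 4 h ranged from −0.323 to 0.015.

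A block for each time and experiment gives no value for untreated cultures, nor do only the arrays of a comparison for the mean, late minus early or lists, and array weights were not run for lists. The pseudocount of 64.61 brought the log2 differences of many named genes nearer 0, such as MMP1 at 48 h (−1.75), VIM at 72 h (−2.37) and FKBP5 at 24 h (0.68). That of 16.15 moved by over 1.5 times FKBP5 at 24 h (1.38), 48 h (1.10), 72 h (0.77) and in the mean (1.12), MMP1 at 48 h (−3.08), 72 h (−2.69) and for late minus early (−2.08), ZNF165 at 72 h (1.35) and CYP1B1 in untreated cultures (−1.20). Signal over background limits genes near the floor of the array, such as VIM and MMP1 in treated cultures.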

Other observations

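The list tests of this part were planned, and the lists and genes named here were picked after the results were seen. At 72 h several further groups held changed genes without passing the set test. Of 21 TGF-beta and BMP response genes 7 fell and 2 rose by both counts, the matrix protein TGFBI (−2.15), thrombospondin-1 (THBS1, −1.99), the activin antagonist FST (−1.36) and LTBP2 (−1.004) having the smallest p (median −0.48, adjusted p = 0.0646). Of 30 genes promoting apoptosis 7 fell and 1 rose by both counts, with TNFSF10, the death ligand TRAIL, at −2.25, the inflammatory caspase CASP4 at −1.64, TP53I3 at −1.38 and FADD at −0.55 (adjusted p = 0.0854). Of 18 genes inhibiting apoptosis BAG1 (1.02) and MCL1 (0.64) rose (3 rises and 1 fall adjusted over the list alone, adjusted p = 0.232). Oxidative stress genes held 2 rises, HMOX1 (2.16) and the thioredoxin reductase TXNRD1 (1.53), and 4 falls, ME1 (−0.78) and PGD (−0.80) among them, of 17 by both counts (adjusted p = 0.874). In the heat shock and unfolded protein list PPP1R15A (1.21) and DDIT3 (1.04) rose and 3 of 20 fell, HSPA5 (−0.65) and PDIA4 (−0.52) among them (adjusted p = 0.816).

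Steroid and lipid genes moved singly. Of 9 genes of corticosteroid receptors and steroid metabolism HSD11B2 (1.76) and the sulfotransferase SULT2B1 (1.26) rose and NR3C1 (−0.57) fell at 72 h (4 rises and 1 fall adjusted over the list alone, adjusted p = 0.151). Of 20 cholesterol synthesis genes TM7SF2 (1.09) rose and GGPS1 (−0.34) fell by both counts (median −0.04, mean 0.01, adjusted p = 0.992). Of 24 genes of fatty acid and epidermal lipid synthesis 5 fell and 0 rose by both counts at 72 h, with FABP5 (−0.68), DGAT1 (−0.38), FADS3 (−0.49) and ACLY (−0.66) among them (adjusted p = 0.215), while the lipid droplet protein PLIN2 (1.66) and the ceramidase ASAH1 (1.16) rose at 24 h.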
